A study of Drosophila melanogaster with 4 samples.

How the data were processed

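H3K9me1, the monomethylated form of a lysine in the tail of histone H3, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from heads of mixed adult Drosophila melanogaster of the wild-type Oregon-R strain. The labels name 2 ChIP libraries, made with an antibody marked as a new lot, and 2 input libraries, each numbered 1 and 2. Per the labels' protocols, flies were grown in population cages, heads were collected with sieves, and chromatin was crosslinked with formaldehyde and sonicated. The sexes of the flies were not given in the labels, and nothing in them says that the replicates came from separate fly populations, so the spread between replicates may be technical.

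Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Per the labels, each input library served the cluster calls of the ChIP library with its number. The deposited values are lists of enriched clusters for ChIP replicate 1, for ChIP replicate 2 and for the whole series, on FlyBase release 5 per the file headers. Each cluster carries a signed score given by the authors, positive in enriched clusters and negative in the few regions typed as depleted. The scale of the deposited score, the cluster caller, its threshold and the way the replicates were combined into the series list were not given in the sources used here. The score was therefore used to describe, rank and filter clusters within a list. The series list was read as the authors' pooled set, with no n and no SD. Read counts were not analysed here, so the depth of each library is unknown and no counting interval could be given for any cluster.

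Sequence lengths came from the file headers. Region classes were fixed before the data were examined: the arms 2L, 2R, 3L, 3R and X without the 1 Mb at their centromeric end, that proximal 1 Mb, chromosome 4, the Het sequences of assembled heterochromatin, and the unplaced sequences U and Uextra. Coverage was the percent of bases under clusters, given as mean ± SD over the 2 replicates. The overlap of the replicates was measured in bases (the Jaccard index, shared bases over bases in either list) and in clusters sharing at least 1 bp, with a one-sided permutation test of 1000 circular shifts of replicate 2 within each sequence. The test was checked on simulated lists of 15335 clusters: 1 of 20 simulations with no shared clusters passed the 0.05 threshold, as did 3 of 3 with 5% and 3 of 3 with 50% of clusters kept. The simulations placed unshared clusters at random along each arm and used fewer than 1000 shifts. They therefore do not check the test on lists that share only broad differences in cluster density. The coverage of chromosome 4 was ranked among 10000 random windows of its length on the whole of the 5 arms, proximal ends included. For the proximal windows, the mean coverage over the arms was ranked among 10000 means of 1 random window of 1 Mb per arm. In an alternative added after the data were seen, random windows came from the arms outside the proximal 1 Mb. The ranking was planned as a one-sided permutation test with no direction written down. Both tails are therefore given, and the lower tail was chosen after the data were seen.

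Several comparisons were chosen after the data were examined: X against the autosomal arms, the proximal windows of 2L, 2R and 3L taken alone, the cluster-free stretches and the placement of depleted regions. X and autosomal arms were compared in 1 Mb windows by a two-sided permutation test with 100000 resamples, and intervals came from 2000 bootstrap draws of windows. Neighbouring windows are not independent, so these p-values are smaller than independent windows would give. Cluster-free stretches of at least 50 kb were compared with 1000 reorderings of each replicate's clusters and gaps. P-values within a family were adjusted by the Benjamini-Hochberg method.

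Named regions followed a rule fixed before the data were examined. Among series clusters overlapping a cluster in each replicate, it took the 5 with the highest score and the 5 widest on the arms, the 3 widest in the proximal windows, the 3 widest on chromosome 4 and the 2 widest on the Het sequences. The gene table used here is on another assembly than the clusters, so positions were not converted, no gene was assigned to a region, and the planned tests of annotated features, covered genes and gene lists were not run. Alternatives covered the score threshold, cluster width, overlap rule, joining of clusters, window width, choice of list and leaving out each replicate. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures Matplotlib 3.10.9.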

Results

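The data were lists of H3K9me1 clusters from 2 ChIP libraries of adult head nuclei, each called against its own input library, and 1 list for the whole series. H3K9me1 clusters were numerous and short and lay almost entirely on the chromosome arms. Replicate 1 held 15404 clusters and replicate 2 held 14643, a mean of 15023.5 ± 538 (SD, n = 2). Of these, 99.8% and 99.9% lay on the 5 arms and chromosome 4. The clusters covered 40.2 ± 3.28 Mb (SD, n = 2), or 33.4 ± 2.72% of the arms and chromosome 4. Median cluster width was 2061 bp in replicate 1 and 1995 bp in replicate 2, and the widest clusters reached 56.7 kb and 34.4 kb. The median authors' score was 0.610 and 0.589. Read depth is unknown for all libraries, so a region without a cluster is a region without a call, not one shown to lack the mark.

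The replicates placed H3K9me1 in largely the same parts of the genome. They shared 31.5 Mb of covered sequence, and their base-level Jaccard index was 0.642. After circular shifts of replicate 2 the index averaged 0.203 and did not exceed 0.243, so the observed value was 3.17-fold above the shifted mean (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Of the replicate 1 clusters, 77.8% touched a replicate 2 cluster, against 53.2% on average after shifting. Of the replicate 2 clusters, 85.6% touched a replicate 1 cluster. Scores also ranked alike across the 11987 overlapping cluster pairs, with Pearson's r of 0.742 and Spearman's rho of 0.708. These correlations are across clusters, which are not independent replicates, so they carry no p-value. Within the autosomal arms alone rho was 0.678, and within X alone it was 0.509.

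The series list was larger than either replicate and contained nearly all of both. It held 21525 clusters over 65.0 Mb, or 53.9% of the arms and chromosome 4, and included 99.5% of the bases of replicate 1 and 99.6% of those of replicate 2. Of its bases, 48.4% were covered in both replicates, 26.5% in 1 replicate and 25.1% in neither. The 6606 series clusters that touched no replicate cluster, 30.7% of the list, had a median width of 1282 bp and a median score of 0.371. The 10232 that touched a cluster in both replicates had a median width of 3469 bp and a median score of 0.516. How the replicates were combined into this list was not given in the sources used here.

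H3K9me1 clusters covered the chromosome arms broadly and were sparse on chromosome 4, in assembled heterochromatin and in the proximal 1 Mb of 2L, 2R and 3L, but not in that of 3R. Outside the proximal 1 Mb, the arms were covered to 34.6 ± 2.82% (SD, n = 2), from 30.6 ± 2.08% on X to 39.7 ± 2.66% on 2R. Chromosome 4, a small chromosome rich in heterochromatin, was covered to 6.43 ± 0.890%, 5.40-fold below the arms. The proximal windows together were covered to 13.6 ± 0.761%, a ratio to the arms of 0.394 ± 0.0102. Coverage was 0.288 ± 0.122% on the Het sequences and 0.111 ± 0.0230% on the unplaced sequence U, and no list held a cluster on YHet or Uextra.

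Chromosome 4 was covered less than nearly all random windows of its length on the whole arms, proximal ends included, whose median coverage was 36.1% in replicate 1 and 31.9% in replicate 2 (permutation p = 0.0075 for the lower tail in each replicate, Benjamini-Hochberg adjusted p = 0.0077 over 9 tests; 0.99 for the upper tail). The proximal windows were ranked by their mean, against means of 1 random window per arm, so the test does not bear on any single proximal window. Their lower-tail permutation p was 0.0001 in each replicate, the smallest that 10000 draws can give, with an adjusted p of 0.00015 and an upper-tail p of 1. The direction of these tests was not fixed beforehand, and with windows drawn outside the proximal 1 Mb the permutation p for chromosome 4 was 0.0001 in each replicate. The random windows overlap one another, so these p-values depend on the number of draws and are smaller than independent windows could give. Among clusters with at least the median score of their list, the ratio of chromosome 4 to the arms was 0.102, against 0.185 over all clusters.

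The proximal windows differed strongly between arms. The 1 Mb at the centromeric end of the assembled arm was covered to 44.4 ± 2.58% on 3R and 18.0 ± 0.0518% on X. On 2L it was covered to 4.73 ± 0.901% and on 2R to 1.00 ± 0.273%, and neither replicate had a cluster there on 3L. The Het sequences are separate from these windows, and 3RHet was covered to 0.388 ± 0.0895%. The windows therefore do not show coverage next to the centromere itself. The windows of 2L, 2R and 3L together, a subset chosen after these values were seen, were covered to 1.91 ± 0.391%, 18.2-fold below the arms. No p is given for this subset, because it was picked for its low coverage. That ratio to the arms, 0.0549 at 1 Mb, was 0.372 with windows of 2 Mb and 0.0106 with windows of 0.5 Mb.

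**Figure D1:**
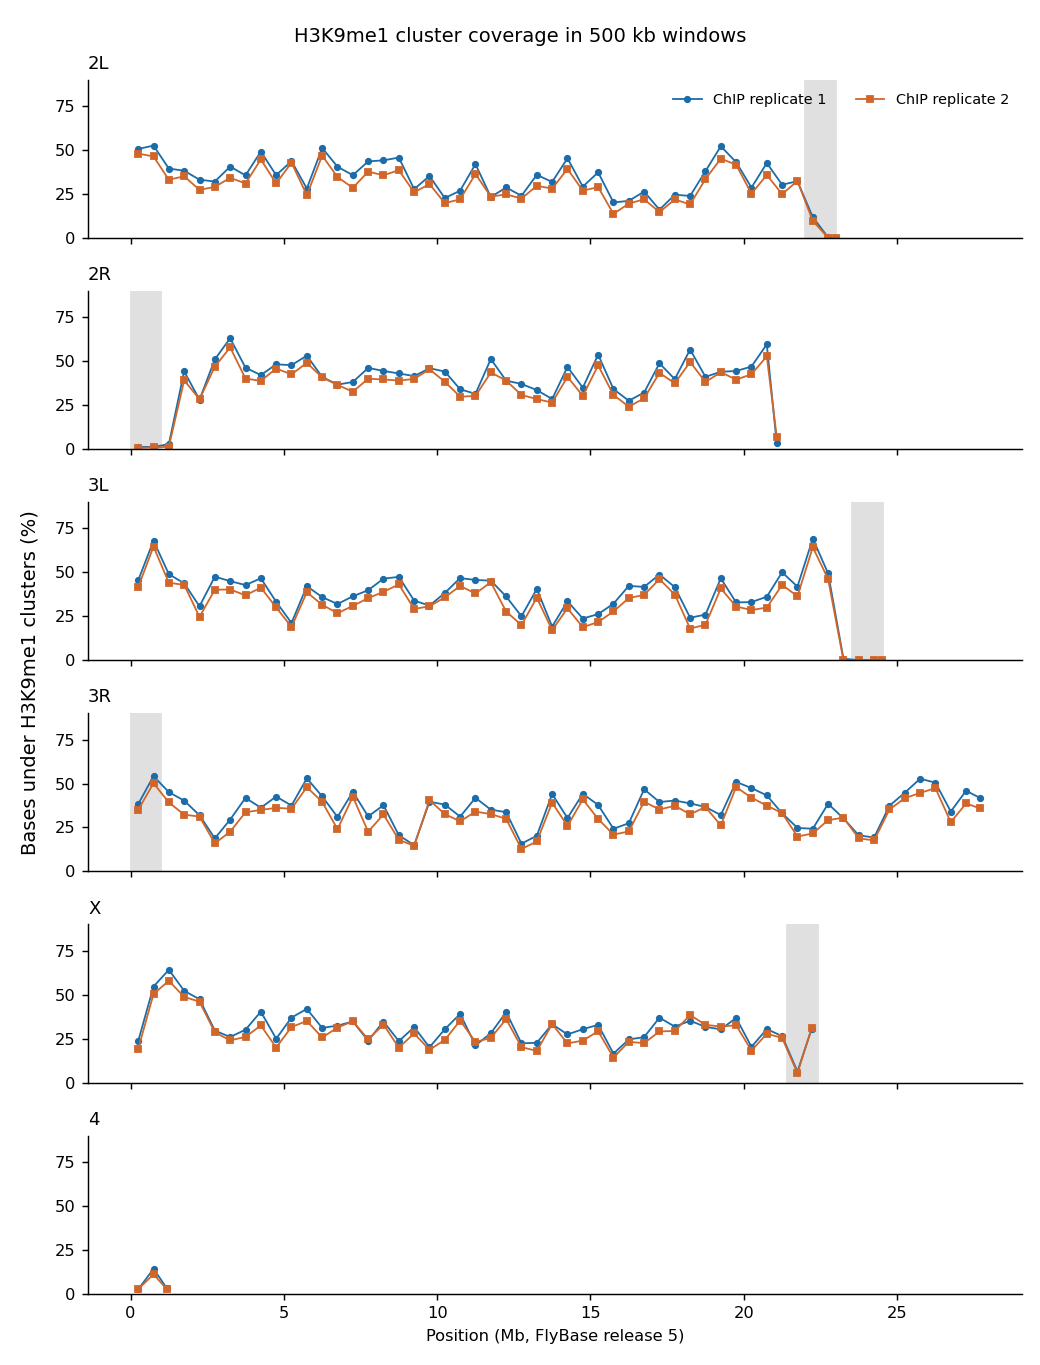
Percent of bases under H3K9me1 clusters (vertical axis) in 500 kb windows along each arm and chromosome 4 (horizontal axis, Mb, FlyBase release 5), with 1 line per ChIP replicate and grey bands marking the proximal 1 Mb. On 3L the window at 22000001 to 22500000 is covered to 69.2% in replicate 1 and 64.3% in replicate 2, and the windows from 23500001 to the end of the arm lie at 0 in both.

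The change near the centromeric end of the assembled arm was abrupt on 3L and 2R. On 3L, coverage was 71.4 ± 3.12% (SD, n = 2) at 22043558 to 22543557, 41.3 ± 2.37% in the next 500 kb and 0.130 ± 0.184% at 23043558 to 23543557. On 2R it was 2.04 ± 1.03% at 1000001 to 1500000 and 41.7 ± 3.60% at 1500001 to 2000000. On chromosome 4 neither replicate had a cluster in the first 0.3 Mb, and coverage was highest, at 20.4 ± 1.02%, at 500001 to 600000.

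**Figure D2:**
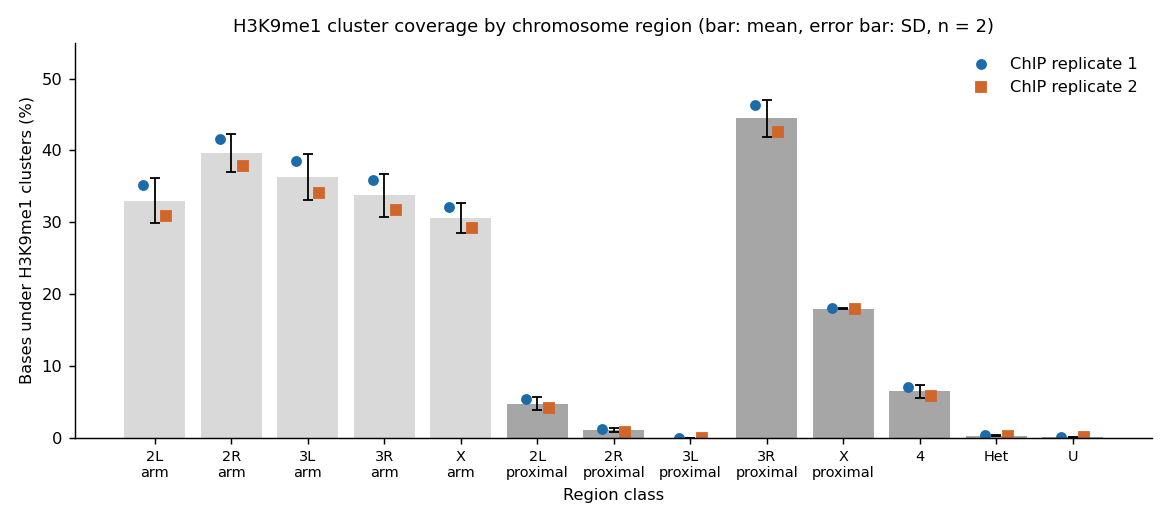
Percent of bases under H3K9me1 clusters (vertical axis) for each arm outside its proximal 1 Mb, each proximal 1 Mb, chromosome 4, the Het sequences and U (horizontal axis); bars are means, error bars SD over 2 replicates, and points the replicates. The 3R proximal window, at 44.4%, is the highest bar, while 2L, 2R and 3L proximal windows lie at or below 4.73%.

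Single regions showed strong and wide H3K9me1 enrichment in both replicates. The highest-scoring region shared by both replicates lay on X at 2023330 to 2026962, with a series score of 1.41 and replicate scores of 1.47 and 1.47. It was followed by 3R at 18581114 to 18596260 (series score 1.32), 2R at 11004315 to 11007921 (1.28), X at 711948 to 722689 (1.27) and 3L at 11953088 to 11958295 (1.27). Scores on X were higher in general, with a series median 0.112 above that of the autosomal arms, more than the gap between the X and 3R regions that lead this ranking. The widest region lay on 3R at 25077752 to 25138460, was 60.7 kb long, and was covered to 97.5% by replicate 1 and 94.1% by replicate 2. The next widest were 3L at 22343374 to 22400184 (56.8 kb), 3L at 770477 to 824741 (54.3 kb), 2R at 1698099 to 1747931 (49.8 kb) and 2L at 7893566 to 7939714 (46.1 kb), each covered to at least 90.8% in both replicates.

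Shared regions were also found in the proximal windows, on chromosome 4 and on the Het sequences, which are much shorter sequences than the arms. The widest in the proximal windows lay on 3R at 914179 to 933269 (19.1 kb), X at 22258038 to 22273191 (15.2 kb) and 3R at 614413 to 629106 (14.7 kb). The 3R regions were covered to at least 83.1% in both replicates, and the X region to 64.7% by replicate 1 and 47.3% by replicate 2. On chromosome 4 the widest was 731289 to 742023, 10.7 kb long with a series score of 0.595, followed by 1196072 to 1199868 (3.80 kb) and 861499 to 864919 (3.42 kb). Replicates 1 and 2 covered 96.4% and 84.4% of the first, 99.1% and 45.4% of the next, and 69.0% and 54.9% of the last. On the Het sequences the widest were XHet 67408 to 69868 (2.46 kb, series score 0.554) and 3RHet 1692950 to 1695353 (2.40 kb, 0.450), each covered to at least 78.1% in both replicates. Genes, exons and introns in these regions were not analysed here, because the gene table used is on another assembly.

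Clusters on X had higher scores than those on the autosomal arms and covered slightly less sequence in both replicates; this comparison was chosen after the data were seen. The median score was 0.754 on X against 0.582 on the autosomal arms in replicate 1, and 0.714 against 0.567 in replicate 2, a mean difference of 0.159 ± 0.0178 (SD, n = 2). The difference was 0.172 (95% bootstrap interval 0.160 to 0.186) and 0.147 (0.136 to 0.160). Over 21 X and 91 autosomal windows of 1 Mb, the two-sided permutation p was 1e-05 in each replicate, the smallest that 100000 resamples can give, with an adjusted p of 2e-05 over 6 tests. Coverage was 30.6 ± 2.08% on X and 35.5 ± 2.99% on the autosomal arms (permutation p = 0.0045 and 0.022, adjusted p = 0.0067 and 0.026). X lay below every autosomal arm, at 32.1% in replicate 1 and 29.2% in replicate 2. The autosomal arms also differed among themselves. They ran from 35.2% on 2L to 41.5% on 2R in replicate 1, and from 30.8% to 37.8% in replicate 2. Because X is a single chromosome, the window test cannot tell a coverage difference specific to X from this spread between arms.

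The coverage difference depended on the clusters counted. In the series list the coverage ratio of X to the autosomal arms was 0.985 (permutation p = 0.6), and among clusters with at least the median score of their list it was 1.29, in the opposite direction. The score difference among those clusters was 0.0727.

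**Figure D3:**
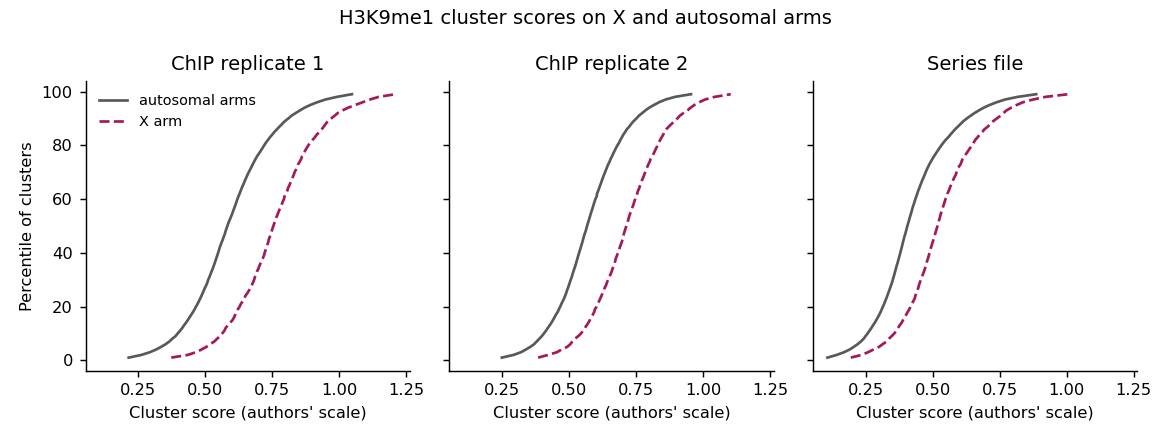
Percentile of clusters (vertical axis) against the authors' cluster score (horizontal axis, authors' scale) for X and the autosomal arms outside the proximal 1 Mb, in each ChIP replicate and the series list. The X line lies to the right of the autosomal line in each panel, with medians of 0.754 and 0.582 in replicate 1.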

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

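Both placement tests given here were chosen after the regions were seen. A small signal appeared in data that the comparisons above do not use: the series list holds 31 regions that the authors typed as depleted, where replicate 1 holds 1 and replicate 2 holds 0. Their scores ran from -0.149 to -0.00380 and their median width was 1463 bp. Of the 31, 30 lay on the arms outside the proximal 1 Mb, with 9 on 3L, 8 on 2L, 7 on 3R, 5 on 2R and 1 on X, and 1 lay on chromosome 4. The lowest scores were on 3R at 13242676 to 13244261 and on chromosome 4 at 533258 to 534779, the latter at -0.147.

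Although typed as depleted in the series list, 22 of the 31 regions touched an enriched cluster of at least 1 replicate, 17 of them a replicate 1 cluster and 8 a replicate 2 cluster. Circular shifts of the lists gave a mean of 17.0 and at most 25 (one-sided permutation p = 0.035, Benjamini-Hochberg adjusted p = 0.07 over 2 tests), so the excess did not pass the adjusted threshold. Series clusters covered 50.1% of the 10 kb on either side of these regions, against 52.8% after shifting (one-sided permutation p = 0.74, adjusted p = 0.74).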

How the results depend on the processing

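Settings for X, for the proximal windows of 2L, 2R and 3L, and for overlap or random windows outside the proximal windows were chosen after seeing the data. Leaving out each replicate for cluster number, width and covered sequence was not planned either. Across the alternatives, 76 values kept their direction and side of the threshold or moved within their spread, 13 moved further, 2 lost the threshold and 1 reversed. Of the 76, 12 were under the 1 kb minimum width, which removed no cluster. Untested values with 1 replicate left out always lie within the SD of 2 replicates, so they could not count as moved. The 76 also include the 2L, 2R and 3L proximal windows, picked for low coverage. Their ratio to the arms went from 0.0549 to 0.372 with windows of 2 Mb. The tests of replicate overlap and of coverage of chromosome 4 and of the 5 proximal windows together passed under every setting run. Under 50% reciprocal overlap, 65.9% and 69.3% of clusters were shared and the score rho was 0.753. Among clusters with at least the median score of their list, 7514 clusters covered 26.0 Mb on average, and 28.7% of series bases lay in neither replicate. The Het and U ratios to the arms were then 0.00172 and 0.00266, chromosome 4 fell to 0.102 and the 2L, 2R and 3L proximal windows to 0.0281. Few clusters carry these ratios, even before that threshold. Replicates 1 and 2 held 20 and 11 on Het, 6 and 5 on U, and 43 and 39 on chromosome 4. The 2L, 2R and 3L proximal windows held 32 and 24. In the series list the Het and U ratios were 0.0144 and 0.00590. The cause of these shifts was not tested, apart from the lower number of clusters that the threshold itself sets.

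The X to autosome coverage ratio was 0.985 in the series list, where the cause was not tested, and reversed to 1.29 with the common score threshold. That threshold keeps more X clusters because X scores are higher: with the threshold set within X and within the autosomes, a setting added after the reversal was seen, the ratio was 0.830, no longer past the threshold in replicate 2 (permutation p = 0.072; 0.017 in replicate 1). The score difference was above 0 in each list and setting run, from 0.0324 (series list, at least the median score) to 0.185 (replicate 1, clusters of at least 5 kb). Other settings for annotated features, covered genes and gene lists were not run. No paired analysis was possible because the reads of the inputs were not analysed here and each input entered only the cluster calls of its ChIP library. Unknown depth limits every statement on regions without clusters.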

Other observations

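The tests of X scores, sparse regions and cluster-free stretches were chosen after those patterns were seen; the tests of sparse regions and of score scatter by cluster width were also chosen after the results they bear on. Long stretches of the arms carried no H3K9me1 cluster in either replicate. Outside the proximal windows there were 38 shared cluster-free stretches of at least 50 kb, 3.35 Mb in all, with a median length of 62.6 kb. The longest, 3L 23252622 to 23543557 (290.9 kb), is cut by the boundary of the proximal window, and the stretch without a replicate cluster runs on to the end of the arm at 24543557, 1.29 Mb in all. Others were 2R 1209907 to 1498757 (288.9 kb), 3L 23011813 to 23251320 (239.5 kb), 2L 21399838 to 21617013 (217.2 kb), 2R 2229273 to 2389649 (160.4 kb) and 3R 12615564 to 12746006 (130.4 kb). The stretches named on 3L, 2R and 2L lie near the sparse proximal windows of those arms and may be part of the same pattern. Series clusters covered a median of 5.65% of the 38 stretches, and 2 of the 38 held no base under a series cluster.

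For the cluster-free stretches, coincidence of gaps was not tested in a way that decides. Independent reorderings of each replicate's clusters and gaps gave a mean of 0.182 Mb and at most 0.605 Mb, in at most 8 stretches (one-sided permutation p = 0.001, the smallest that 1000 reorderings can give). The reorderings remove the agreement between the replicates, which the overlap of their clusters had already shown, so an excess of shared stretches was fixed in advance. Sequence to which reads could not be assigned was not tested there, and no biological explanation was tested.

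Higher scores on X are unlikely to come from a loss of low-scoring clusters alone, since clusters above the autosomal 75th percentile of score covered 1.59 times as much of X as of the autosomal arms in replicate 1 and 1.69 times in replicate 2 (permutation p = 1e-05 in each, the smallest possible). Score noise from lower depth on X stays open. Scores differed more between replicates on X than on the autosomes. The SD of the difference was 0.147 against 0.114 in narrow clusters, and 0.123 against 0.0929 in wide ones, of at least 5 kb. Whether depth causes this was not tested. Clusters of at least 5 kb kept 1.08 times the full difference in replicate 1 and 1.10 times in replicate 2 (lower 95% bounds 0.886 and 0.961). Both lay above the 0.5 that had been set as the bound against noise. On X these clusters were few, 171 in replicate 1 and 141 in replicate 2. Their scores on X scattered between replicates 0.838 times as much as those of narrower clusters (91 wide pairs, 95% bootstrap interval 0.706 to 0.949). Noise therefore need not bring the difference below 0.5. A first criterion, that this interval lie below 1, was met and would have counted against noise; it was replaced after the value was seen, because the interval also reaches above the lower bound of replicate 1. A constant offset of the ChIP to input baseline remains a candidate explanation: the difference at the 10th percentile was 0.973 times that at the 90th on average (1.04 and 0.906 in the replicates). This reading holds only if such an offset adds a constant to the score, as for a log ratio, and the scale of the score is not known. Whether an offset also fits the lower coverage of X was not tested, the sexes of the flies were not given, and no biological explanation was tested.

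For the few clusters on chromosome 4, the Het sequences and the proximal windows of 2L, 2R and 3L, weaker detection stays open. The median score of clusters called there lay below that of clusters of like width on the autosomal arms, with a mean difference of -0.0447: 0.483 against 0.534 (95% of draws 0.509 to 0.559) in replicate 1, and 0.493 against 0.531 (0.506 to 0.552) in replicate 2. This decides nothing, because only called clusters have a score and neither its scale nor the calling threshold is known. Series calls were present in 8.98% of 1325 tiles of 10 kb there and in 95.6% of tiles on the arms, and sequence to which reads could not be assigned cannot be told apart from sequence with reads and no enrichment, because cluster lists hold no read counts. No biological explanation was tested.

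The series list also held 5 clusters tied at its top score of 3.01, on 2L, 2RHet, 3L (2 clusters) and 3R, none of which touched a replicate cluster. They were 1001 to 1080 bp wide, where the narrowest cluster of the list had 1001 bp. Of the 12 series clusters scoring above 1.7, none touched a cluster in both replicates. Of the series clusters, those in both replicates had a median score 0.145 above those in neither (95% bootstrap interval 0.138 to 0.152, 500 draws). They were also wider, with a median of 3469 bp against 1282 bp, and score rose with width in this list (Spearman's rho 0.598). The score gap was not adjusted for width.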
